A study of Homo sapiens with 60 samples.

How the data were processed

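The study sequenced total RNA from 60 human lymphoma cell line libraries after ribosomal RNA depletion with a stranded kit that keeps short RNA, and each library has a gene table and a microRNA table. KARPAS 1106P (called K1106P here) and U2940 are primary mediastinal B-cell lymphoma lines, and HDLM2 and L428 are Hodgkin lymphoma lines. Each line was kept for 48 h in medium alone or with 1 of 4 drugs at doses the labels place at or near the concentration that inhibits growth by 50%. The drugs were rituximab (anti-CD20 antibody, 200 ug/ml), brentuximab vedotin (anti-CD30 antibody carrying a tubulin toxin, 25 ng/ul), ibrutinib (BTK inhibitor, 2.5 uM) and prednisone (a glucocorticoid, 60 ug/ml). There were 3 replicates in each of 20 groups, and all 60 libraries were assigned from their labels.

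Per the submitters' processing notes, the authors used bcl2fastq 1.8.4, cutadapt 1.12, Bowtie2 2.2.5, Partek 9.0 and DESeq2 (no version given) with genome build hg38. The notes do not say which tool made which step, in what order, or with which annotation. The deposited gene tables hold 27394 entries in a signal that the values show to be estimated counts divided by a median-of-ratios size factor taken over the 60 libraries. The deposited microRNA tables hold 2130 mature microRNAs in a signal that behaves as the authors' estimated counts times a library factor that could not be identified. In each table of genes, 95.2% to 96.0% of the values up to 50 reads lay within 0.02 of a whole number of steps, and in those of microRNAs 75.4% to 89.8% did. A step, the value of 1 read, was worth 0.342 to 2.47 units in the gene tables and 67.8 to 589 units in the microRNA tables. These values are not whole counts, so the count-based test planned for counts was not run, and its fallback, limma-trend, was used as fixed before the data were examined. No genome or coordinates were used, so genes are named by symbol only.

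The 37 ribosomal RNA entries were left out of every test and kept for the share of signal they took. In each line, the 15 libraries were fitted together on log2(value + 1), keeping genes at 10 or more in at least 3 libraries, with group means and limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, robust). Each drug was compared with the untreated cells of its line, which gave 16 comparisons, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no fold minimum. Errors given after log2 fold changes are standard errors from this fit, and errors after levels are standard deviations of 3 replicates. Whether a drug's effect differed between lines was tested with a limma-trend F test on 3 degrees of freedom over the 24 libraries of that drug and of untreated cells. Single pairs of lines were compared for the 6 fixed genes, with p adjusted over all such pairs and drugs. Untreated lines were compared by a limma-trend F test over 12 libraries. Line and sequencing set cannot be told apart in either test.

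Before the data were examined, 29 gene lists and 4 microRNA lists were fixed. A list with 5 or more tested members was tested with camera at a preset correlation of 0.01, adjusted over all lists and all 16 comparisons, with fry and with camera at an estimated correlation beside it. The list of mitochondrially encoded genes matched 0 entries, and the list of stromal and epithelial markers had too few tested members in all 4 lines.

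The rule for named genes was also fixed beforehand. It takes CD274, PDCD1LG2, MS4A1, TNFRSF8, BTK and NR3C1 everywhere. It adds the 5 largest rises and 5 largest falls per line with rituximab (4 and 4 with other drugs) among genes past the threshold with a mean of at least 5 CPM (counts scaled to the library total) and no overlap between the replicates of both groups. It also takes up to 3 rises and 3 falls per list described, up to 6 genes changed one way in at least 3 lines, and 5 genes per test between lines. For microRNAs it takes 3 rises and 3 falls with a mean of at least 50 CPM and called members of the list of microRNAs described as acting on PD-L1. Genes outside this rule are said to be chosen after their values were seen.

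Alternatives planned beforehand were leaving out each library in turn, no filter on low values, a pseudocount of 0.1, only the 6 libraries of both groups, a replicate block, and for microRNAs the library size of the gene table. Added after seeing the data were voom weights on reads recovered from the value steps, scaling to the total outside ribosomal RNA or to the microRNA total, the log odds of the ribosomal share as a covariate for genes, and leaving out 4 libraries whose ribosomal share lay more than 20 percentage points from both other replicates. The procedure was tested on simulated reads drawn with the untreated means and the replicate spread of each line. Of 100 genes changed 2-fold, 57% to 68% were recovered in the 4 lines, and of 100 changed 4-fold, 84% to 93%, with 3 to 12 wrong calls among 12504 to 12848 genes. For microRNAs, 5% to 66.7% of 4-fold changes were recovered, with 0 to 2 wrong calls among 282 to 418 and, in U2940, 1 call for a drug left unchanged. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Because most microRNAs have few reads and a pseudocount of 1 lies far below the value of 1 read, microRNA fold changes from levels near 0 depend on that pseudocount.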

Results

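The 60 libraries from 4 lymphoma cell lines, 3 per group at 48 h, each gave a level for 27394 gene entries and 2130 microRNAs. The total of the gene table ran from 2346140 to 32680700 normalized units per library (median 14085800), and the part outside ribosomal RNA from 2090770 to 3150620. From the size of the value steps, the libraries held an estimated 1.17 to 6.67 M reads outside ribosomal RNA (median 2.42 M) and 2744 to 8773 microRNA reads. Between 16374 and 22626 gene entries and between 180 and 500 microRNAs were above 0 in a library. Gene levels below are the authors' normalized estimated counts, given as mean ± SD with n = 3 per group.

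Ribosomal RNA took 8.44% to 91.3% of the gene-table signal (median 81.7%), and this share moved with some treatments. In K1106P it was 89.5% ± 0.437 untreated, 74.0% ± 7.08 with rituximab, 82.2% ± 4.51 with brentuximab vedotin, 52.3% ± 38.9 with ibrutinib and 74.6% ± 10.4 with prednisone. In U2940 the group means lay between 85.2% and 90.1%, and in L428 between 74.4% and 85.9%. In HDLM2 it was 58.4% ± 33.3 untreated, 60.4% ± 17.6 with rituximab, 87.3% ± 3.26 with brentuximab vedotin, 47.8% ± 17.1 with ibrutinib and 14.5% ± 3.48 with prednisone. In 4 libraries (HDLM2 untreated replicate 1, HDLM2 rituximab replicate 2, HDLM2 ibrutinib replicate 3 and K1106P ibrutinib replicate 3) the share lay more than 20 percentage points from both other replicates.

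**Figure D1:**
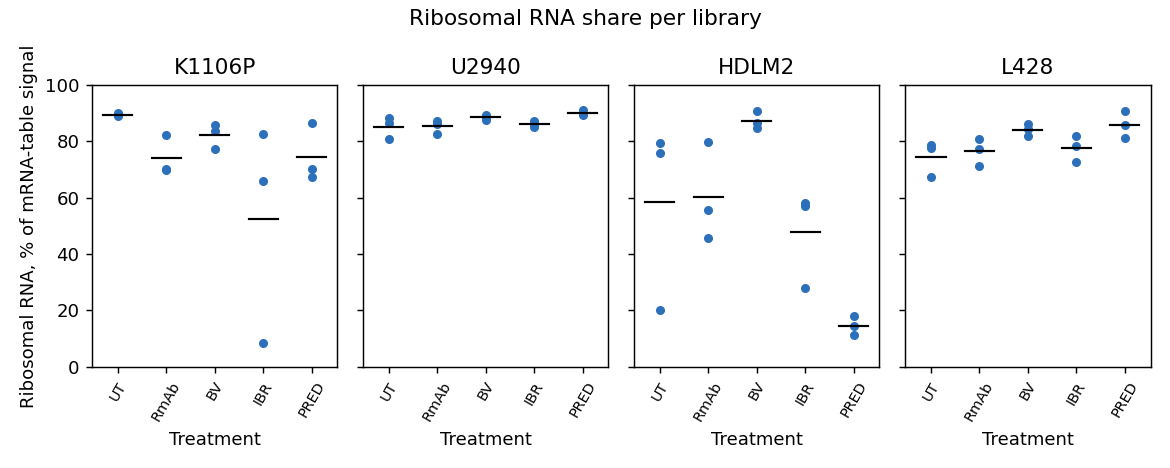
Share of gene-table signal in ribosomal RNA (percent, vertical axis) in each of the 60 libraries, by cell line and treatment; points are libraries and bars are group means. The HDLM2 prednisone libraries lie lowest as a group, with a mean of 14.5%.

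The untreated lines differed in the genes the drugs act on. MS4A1, which encodes CD20, the target of rituximab, stood at 4009 ± 288 in K1106P and 3950 ± 771 in U2940, and at 1.23 ± 1.15 in HDLM2 and 0.875 ± 0.975 in L428. BTK, the kinase that ibrutinib blocks, had the same split, with 312 ± 4.92 and 362.6 ± 19.6 in the B-cell lines and less than 1 unit in both Hodgkin lines. TNFRSF8, which encodes CD30, the target of brentuximab vedotin, was 25.5 ± 6.6 in K1106P and 32.6 ± 3.54 in U2940, against 1680 ± 201 in HDLM2 and 473.5 ± 46.6 in L428. NR3C1, the glucocorticoid receptor, was present in all 4 lines at 185.7 to 667.9. CD274, which encodes PD-L1, was 280.9 ± 21.7 in K1106P, 203.3 ± 19.1 in U2940, 360.2 ± 157 in HDLM2 and 11.5 ± 1.86 in L428, and PDCD1LG2, which encodes PD-L2, was 159.7 ± 28.2, 66.2 ± 20.2, 221.2 ± 96.2 and 6.79 ± 1.57 in the same order. All 6 genes differed between the untreated lines (limma-trend F test, adjusted p from 5.4e-16 for TNFRSF8 to 2.35e-08 for PDCD1LG2).

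The drugs differed widely in how many genes passed limma-trend at an adjusted p under 0.05. Of 13476 genes tested in K1106P, rituximab changed 4267 (2260 up, 2007 down), ibrutinib 5123 (2533 up, 2590 down), prednisone 3909 (1985 up, 1924 down) and brentuximab vedotin 1. Of 12968 in U2940, prednisone changed 3435 (1628 up, 1807 down), ibrutinib 904 (518 up, 386 down), rituximab 3 and brentuximab vedotin 2. Of 13162 in HDLM2, prednisone changed 6462 (2498 up, 3964 down), brentuximab vedotin 3324 (1604 up, 1720 down), ibrutinib 63 (7 up, 56 down) and rituximab 0. With rituximab 1249 had an unadjusted p under 0.05, and 0 passed by voom, 1 with a pseudocount of 0.1 and 1366 without untreated replicate 1. Of 12885 in L428, prednisone changed 2892 (1306 up, 1586 down), ibrutinib 164 (49 up, 115 down), brentuximab vedotin 3 and rituximab 0, with 413 at an unadjusted p under 0.05 and 1 called by voom. At 2-fold or more the counts were 1117, 1180 and 1106 for rituximab, ibrutinib and prednisone in K1106P. They were 804 and 179 for prednisone and ibrutinib in U2940, 1704 and 722 for prednisone and brentuximab vedotin in HDLM2, and 460 for prednisone in L428. The labels do not say how the replicates were made, so every p measures only the spread between these libraries.

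The balance of rises and falls depended on the scaling. With values scaled to the total outside ribosomal RNA, K1106P rituximab gave 1154 up and 2451 down, K1106P ibrutinib 3368 up and 1544 down, U2940 prednisone 947 up and 2817 down, HDLM2 brentuximab vedotin 767 up and 3976 down, HDLM2 prednisone 4039 up and 2810 down, and L428 prednisone 766 up and 2688 down. The median log2 fold change of all genes under that scaling was −0.08, 0.17, −0.13, −0.24, 0.13 and −0.15 in the same order, and the changes given below are relative to the deposited scaling. With the ribosomal share as a covariate, prednisone changed 1544 genes in U2940, 3568 in HDLM2 and 998 in L428.

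**Figure D2:**
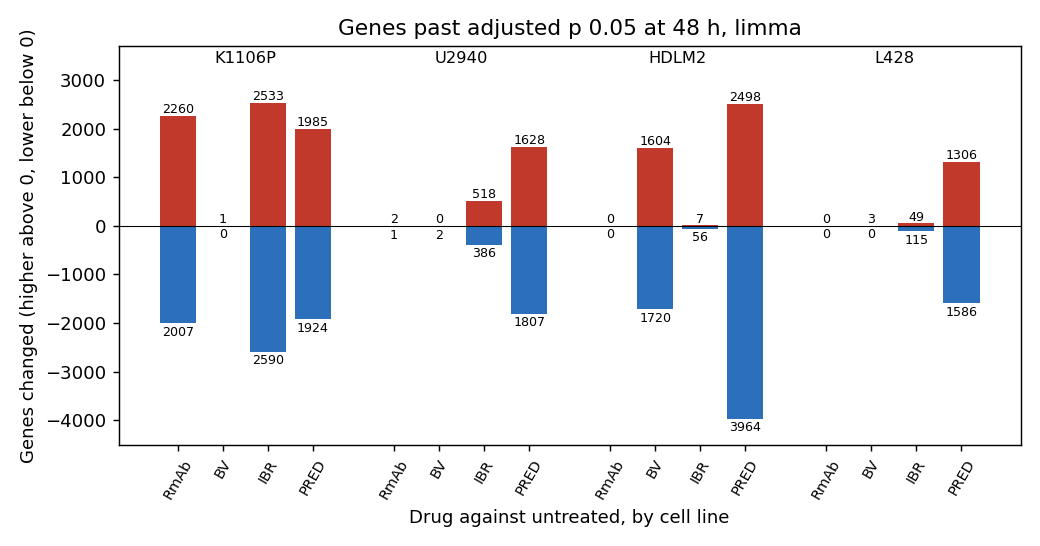
Genes past an adjusted p under 0.05 (vertical axis) per line and drug against its untreated cells, with rises and falls as separate bars (n = 3 per group). Prednisone passed 2892 to 6462 genes in every line, and rituximab passed 4267 in K1106P and 3 or fewer elsewhere (1366 in HDLM2 without untreated replicate 1).

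The series concerns PD-L1 after anti-CD20 treatment of mediastinal lymphoma cells, so both PD-1 ligand transcripts were compared throughout. In K1106P CD274 fell with rituximab from 280.9 ± 21.7 to 142.9 ± 18.4 (log2 fold change −0.98, SE 0.116, limma-trend adjusted p 2.18e-06), and PDCD1LG2 fell from 159.7 ± 28.2 to 65.4 ± 18.5 (−1.30, SE 0.172, limma-trend adjusted p 8.97e-06). CD274 also fell in K1106P with ibrutinib to 147.3 ± 7.95 and with prednisone to 182.7 ± 5.02. In U2940 CD274 fell with ibrutinib to 122.4 ± 21.9 and with prednisone to 125.4 ± 18.6, while with rituximab its log2 fold change was −0.02 (SE 0.15, limma-trend adjusted p 0.996). In HDLM2 CD274 rose with brentuximab vedotin from 360.2 ± 157 to 689.8 ± 27.8 (1.04, SE 0.248, limma-trend adjusted p 0.0103), and by 0.67 without untreated replicate 1. Without that replicate CD274 passed downwards with rituximab (−0.57 to −0.93), ibrutinib (−0.68 to −1.05) and prednisone (−0.21 to −0.58). PDCD1LG2 did too (−0.92, −1.31 and −0.85). Untreated replicates 2 and 3 held 79.6% and 75.7% ribosomal RNA, rituximab ones 45.7% to 79.9%, so drug and share were not separated. Untreated MS4A1 was 1.23. Without untreated replicate 2 PDCD1LG2 passed upwards with brentuximab vedotin (0.97). PDCD1LG2 in K1106P with ibrutinib (−0.48, limma-trend adjusted p 0.0312) lost its call without ibrutinib replicate 1 (0.11) or 2 (0.0682), without untreated replicate 1 (0.123) or 2 (0.11), and with scaling outside ribosomal RNA (0.14). With the ribosomal share as a covariate CD274 lost its calls with brentuximab vedotin in HDLM2 (0.65, limma-trend adjusted p 0.0587) and prednisone in U2940 (−0.48, 0.129), and PDCD1LG2 passed with ibrutinib in HDLM2 (−0.87, 0.00766). In L428, where both ligands were near the lower limit, neither passed with any drug. Between lines, the rituximab effect on PDCD1LG2 differed (limma-trend F test adjusted p 0.00648), by −1.29 between K1106P and U2940 (limma-trend adjusted p 0.0303) and −2.0 between K1106P and L428 (0.00128), and was not shown to differ between K1106P and HDLM2 (−0.71, 0.327). The effect on CD274 was not shown to differ with rituximab (F test adjusted p 0.109, limma-trend), ibrutinib (0.703) or prednisone (0.687), and differed with brentuximab vedotin (0.0175), where HDLM2 exceeded K1106P by 1.26 on the log2 scale.

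**Figure D3:**
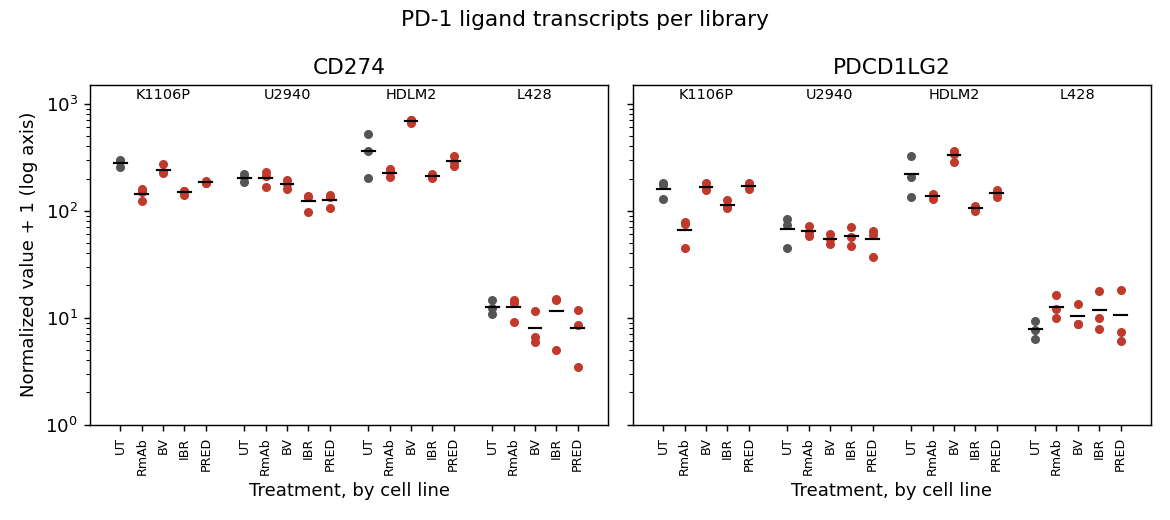
CD274 and PDCD1LG2 in each library (normalized value + 1, log axis) by line and treatment; points are libraries and bars are group means of 3. In K1106P the rituximab libraries lie below the untreated ones for both genes.

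With rituximab in K1106P, PRDM1, a transcription factor that drives plasma cell differentiation, rose 12.3-fold from 48.7 ± 2.38 to 609 ± 35.2 (log2 fold change 3.62, SE 0.161, limma-trend adjusted p 7.75e-13). The other 4 largest rises were the chemokine CCL3 (6.41 ± 6.8 to 155 ± 49.3), its paralog CCL3L1 (1.04 ± 1.8 to 30.4 ± 11.4), the ERK phosphatase DUSP4 (13.5-fold) and the cytokine signalling inhibitor SOCS3 (11.8-fold). The 5 largest falls were LRCH2 (−3.13), the protocadherins PCDHGA5 (−3.03) and PCDHGA8 (−2.55), ECEL1 (−2.61) and the homeobox gene NKX2-3 (−2.57), all at levels of 25.2 to 37.6 in untreated cells. ECEL1 lost its call (limma-trend adjusted p 0.0291) without rituximab replicate 3 (0.124) or untreated replicate 1 (0.078) or 2 (0.0784). MS4A1 fell from 4009 ± 288 to 2602 ± 695 (−0.66, SE 0.142), and by 0.42 on the log2 scale without rituximab replicate 3. TNFRSF8 (0.63, limma-trend adjusted p 0.0347) lost its call without rituximab replicate 1 (0.0891) or 2 (0.105), without untreated replicate 1 (0.0503) or 3 (0.182), and with scaling outside ribosomal RNA (0.0826). The rise of BTK (0.48) was lost with that scaling too (limma-trend adjusted p 0.0585).

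Of 19 immediate early and early response genes, 13 rose and 1 fell with rituximab in K1106P over all genes, and 15 and 1 when adjusted over the list alone (camera adjusted p 7.64e-09, and adjusted p = 0.117 with an estimated correlation). EGR2 rose from 55.8 ± 0.154 to 346.9 ± 22.6, JUNB 3.71-fold and EGR1 2.87-fold. Of 32 NF-kB target genes, 19 rose and 5 fell over all genes, and 21 and 5 adjusted over the list alone (camera adjusted p 3.78e-06, and adjusted p = 0.256 with an estimated correlation). The cytokine subunit EBI3 rose 4.39-fold, while NFKBIZ (−0.79) and the lymphotoxin gene LTB (−1.05) fell. Of 23 JAK-STAT feedback genes and STAT targets, 14 rose and 4 fell over all genes, and 16 and 4 adjusted over the list alone (camera adjusted p 0.000131, and adjusted p = 0.155 with an estimated correlation). CCND2, a G1 cyclin, rose 9.50-fold and the transcription factor BATF 5.43-fold, while BCL6, the germinal centre repressor, fell from 746.1 ± 21.2 to 356.5 ± 16.8. Under scaling outside ribosomal RNA these 3 lists kept their direction, with 13, 19 and 11 members up.

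Of 30 genes of the unfolded protein and integrated stress response, 17 rose and 1 fell with rituximab in K1106P over all genes, and 19 and 1 adjusted over the list alone (camera adjusted p 6.89e-08, and adjusted p = 0.117 with an estimated correlation). The chaperone HSP90B1 rose from 520.9 ± 34.4 to 1814 ± 526 and the cystine transporter SLC7A11 3.43-fold. Of 9 plasma cell markers, 4 rose and 2 fell by both adjustments, over all genes and adjusted over the list alone (camera adjusted p 0.0419, and adjusted p = 0.415 with an estimated correlation). IRF4 rose from 743.3 ± 41.7 to 1704 ± 55.7 and XBP1, a driver of the secretory programme, 2.67-fold. Of 83 ribosomal protein genes, 57 rose and 0 fell over all genes, and 67 rose and 1 fell adjusted over the list alone (camera adjusted p 8.34e-13, and adjusted p = 0.496 with an estimated correlation), at a median log2 fold change of 0.37, and scaling outside ribosomal RNA left 18 up and 1 down. Of 17 genes of MHC class I presentation, 11 rose and 1 fell over all genes and adjusted over the list alone (camera adjusted p 0.00566, and adjusted p = 0.496 with an estimated correlation), among them HLA-B (0.99) and HLA-C (1.08). The ribosomal RNA share of these libraries was 74.0%, against 89.5% untreated.

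B-cell and survival genes went both ways with rituximab in K1106P. Of 32 B-cell receptor and B-cell identity genes, 8 rose and 10 fell over all genes, and 9 and 11 adjusted over the list alone (camera adjusted p 0.466). CD24 fell from 730.4 ± 12.8 to 191.8 ± 11.8 and FCRL1 4.26-fold, while the adaptor BANK1 rose 3.40-fold. Of 29 BCL2 family and apoptosis genes, 11 rose and 3 fell over all genes, and 13 and 3 adjusted over the list alone (camera adjusted p 0.0451, and adjusted p = 0.318 with an estimated correlation), with 6 up and 4 down under scaling outside ribosomal RNA. BIK, which promotes apoptosis, rose from 7.84 ± 4.26 to 82.7 ± 13.6, and BCL2, which opposes it, 3.74-fold. Of 20 immune checkpoint genes, 1 rose and 6 fell by both adjustments, over all genes and adjusted over the list alone (camera adjusted p 0.0586, fry adjusted p 0.0152).

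Ibrutinib in K1106P lowered proliferation genes. All 34 mitosis and G2/M genes fell over all genes and adjusted over the list alone (camera adjusted p 6.39e-23, and adjusted p = 0.256 with an estimated correlation), among them CDK1, the mitotic kinase, from 483.9 ± 23.3 to 178.2 ± 57.5. Of 34 DNA replication genes, 27 fell over all genes and 29 adjusted over the list alone (camera adjusted p 4.97e-12, and adjusted p = 0.256 with an estimated correlation), and the replication clamp PCNA went from 1198 ± 57.3 to 539.3 ± 186. All 61 replication-dependent histone genes fell over all genes and adjusted over the list alone (camera adjusted p 5.5e-37, and adjusted p = 0.272 with an estimated correlation). Of 83 ribosomal protein genes, 74 fell over all genes and 76 adjusted over the list alone (camera adjusted p 3.11e-17, and adjusted p = 0.431 with an estimated correlation), and 44 fell with scaling outside ribosomal RNA. RPS13 fell by 0.90 on the log2 scale, and by 0.54 on the log2 scale without ibrutinib replicate 1. The ribosomal RNA share of ibrutinib replicates 1, 2 and 3 was 82.5%, 66.0% and 8.44%, against a mean of 89.5% untreated, and the count of 5123 genes was 4491 without ibrutinib replicate 3. With the share as a covariate it was 3960, of which 3568 were among the 5123 in the same direction.

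With ibrutinib in K1106P, 12 of 23 JAK-STAT genes rose and 1 fell over all genes, and 14 and 1 adjusted over the list alone (camera adjusted p 6.67e-06, and adjusted p = 0.117 with an estimated correlation). IL2RA, the interleukin 2 receptor alpha chain, rose from 17.5 ± 1.86 to 175.6 ± 10.2. Of 15 chemokines and cytokines, 8 rose over all genes and 9 adjusted over the list alone (camera adjusted p 4.66e-05, and adjusted p = 0.256 with an estimated correlation), with the T-cell attractants CCL17 (6.22-fold) and CCL22 (3.27-fold) and with LTB (3.39-fold). Of 17 genes of MHC class I presentation, 7 rose over all genes and adjusted over the list alone (camera adjusted p 0.00857, and adjusted p = 0.515 with an estimated correlation), including HLA-C (1.26) and its regulator NLRC5 (1.25). The largest rises were MUC16, a cell surface mucin, from 10.6 ± 3.78 to 334.8 ± 53.1, PGGHG (1.54 ± 1.56 to 48.9 ± 12.6), RUBCNL (12.2-fold) and AS3MT (1.99 ± 2.67 to 29.0 ± 12.7). The largest falls were MIR4488 (−3.29), MIR4508 (−2.83), HIC1 (−2.79) and RELN (−2.74). Without ibrutinib replicate 3, whose ribosomal share was 8.44%, MIR4508, HIC1 and RELN stood at −1.5, −1.95 and −1.55 and lost their calls (limma-trend adjusted p 0.0794, 0.0826 and 0.132). MIR4508 and RELN also lost them without any of ibrutinib replicate 2 (0.0683 and 0.089), untreated replicate 1 (0.117 and 0.101), 2 (0.0963 and 0.102) or 3 (0.0793 and 0.0927), and HIC1 without ibrutinib replicate 2 (0.074) or untreated replicate 1 (0.0656) or 2 (0.0728).

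Prednisone in K1106P raised TSC22D3, the glucocorticoid-induced leucine zipper gene, 8.25-fold from 39.6 ± 2.25 to 334.7 ± 38.7 (log2 fold change 3.04, SE 0.149, limma-trend adjusted p 1.18e-11). Of 23 glucocorticoid receptor targets, 10 rose and 1 fell over all genes, and 10 and 2 adjusted over the list alone (camera adjusted p 0.00209, and adjusted p = 0.272 with an estimated correlation). BCL2L11, which encodes the pro-apoptotic protein BIM, rose from 122.6 ± 8.28 to 419.8 ± 14 and ISG20 7.15-fold. Of 34 mitosis genes 33 fell, and of 34 replication genes 33 fell, over all genes and adjusted over the list alone (camera adjusted p 2.21e-28 and 7.67e-36, and adjusted p = 0.225 and 0.106 with an estimated correlation). Of 61 histone genes, 60 fell over all genes and 61 adjusted over the list alone (camera adjusted p 1.23e-44, and adjusted p = 0.256 with an estimated correlation). MKI67, the proliferation marker, fell from 2105 ± 39.8 to 647.4 ± 43.5 and the nucleotide synthesis enzyme TYMS 3.49-fold. Of 33 type I interferon stimulated genes, 15 rose over all genes and 17 adjusted over the list alone (camera adjusted p 4.72e-05, and adjusted p = 0.545 with an estimated correlation), with IFI6 at 4.85-fold. The other largest changes were MIR1248 (1.08 ± 1.69 to 51.9 ± 37.7), RIMBP3B (9.92-fold) and CORO7-PAM16 (9.27-fold) up, and SNORD14D (−2.56), LRCH2 (−2.42), KREMEN2 (−2.34) and ADGRB2 (−2.29) down. MS4A1 rose by 0.48 on the log2 scale, a call lost without untreated replicate 1 or 3 (limma-trend adjusted p 0.0519 for each).

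Brentuximab vedotin passed 1 gene in K1106P, EGR1, an immediate early transcription factor (62.5 ± 5.0 to 114.3 ± 11.5, log2 fold change 0.86, SE 0.134, limma-trend adjusted p 0.0255), with 763 genes at an unadjusted p under 0.05. That call was lost in every fit without 1 library (limma-trend adjusted p 0.119, 0.488 and 0.0586 without treated replicates 1, 2 and 3, and 0.139, 0.159 and 0.0644 without untreated ones) and with scaling outside ribosomal RNA (0.0524) or its share as a covariate (0.0523). Of 19 immediate early genes, 1 rose over all genes and 2 adjusted over the list alone (camera adjusted p 2.88e-05, and adjusted p = 0.256 with an estimated correlation). None of the 6 fixed genes passed.

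**Figure D4:**
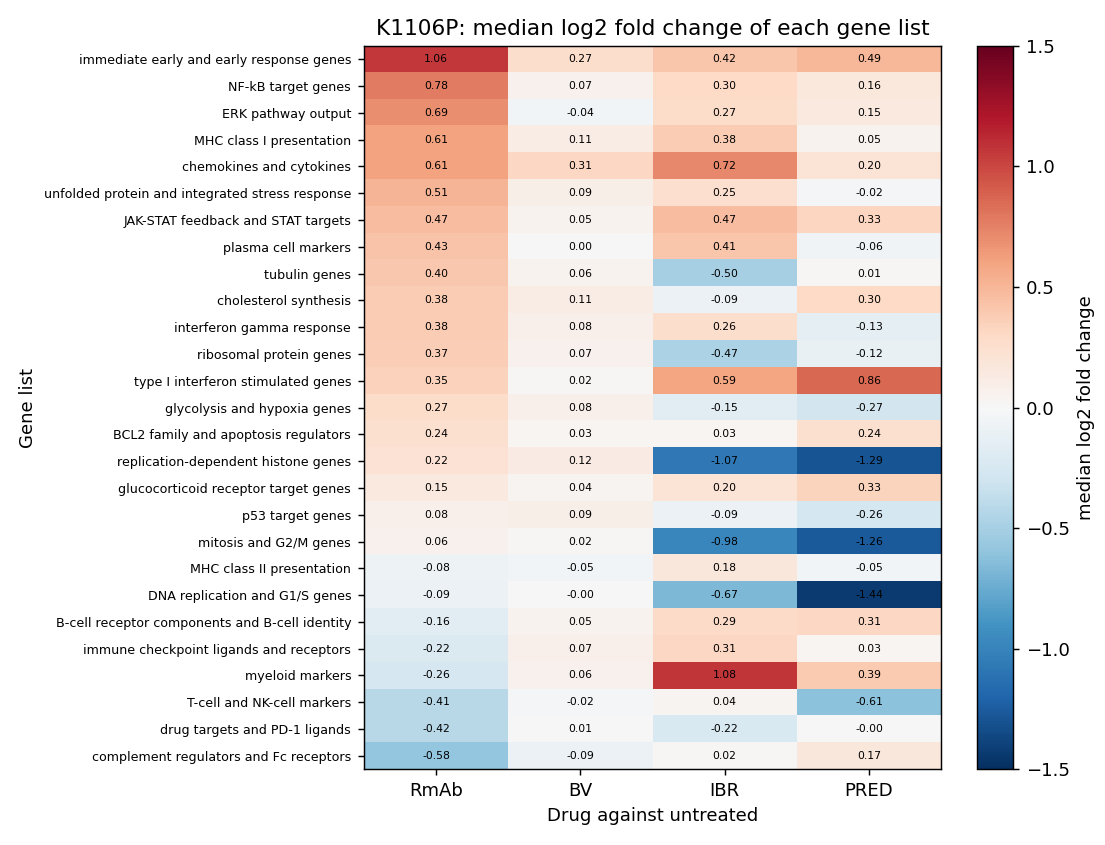
Median log2 fold change (colour) of each gene list (rows) with each drug (columns) in K1106P against untreated cells, n = 3 per group. The histone, mitosis and replication lists are negative with ibrutinib and prednisone, and the immediate early list is highest with rituximab at 1.06.

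In U2940, rituximab passed 3 genes. CCL22, a chemokine that draws regulatory T cells, rose 2.94-fold from 153.9 ± 37.9 to 452.4 ± 111 (log2 fold change 1.55, SE 0.166, limma-trend adjusted p 6.37e-06). TFPI2, a protease inhibitor, went from 129.4 ± 20.8 to 243.8 ± 11 and EML1, a microtubule-binding protein, from 113.5 ± 15.7 to 61.8 ± 8.01. TFPI2 (limma-trend adjusted p 0.0497) lost its call without rituximab replicate 2 (0.239) or 3 (0.403), without untreated replicate 1 (0.219), 2 (0.062) or 3 (0.124), and with scaling outside ribosomal RNA (0.0594) or its share as a covariate (0.0546). EML1 (0.0201 by limma-trend) lost it without rituximab replicate 3 (0.403) or untreated replicate 2 (0.062) or 3 (0.128). The count was 30 without rituximab replicate 1, and 1 without rituximab replicate 3 or untreated replicate 2 or 3. Of 33 NF-kB targets, 1 rose over all genes and 3 adjusted over the list alone, at a median of 0.30 (camera adjusted p 4.71e-10, and adjusted p = 0.272 with an estimated correlation). Of 32 B-cell genes, 0 passed over all genes, and 1 rose and 6 fell adjusted over the list alone (camera adjusted p 6.84e-05, and adjusted p = 0.106 with an estimated correlation). Brentuximab vedotin passed 2 genes, with 545 at an unadjusted p under 0.05. The collagen gene COL4A4 went from 30.8 ± 5.06 to 9.68 ± 2.04, and lost its call (limma-trend adjusted p 0.0165) without treated replicate 2 (0.194) or 3 (0.191) or untreated replicate 2 (0.084) or 3 (0.501), and with that covariate (0.208). The receptor kinase gene EPHB1, chosen after its values were seen, fell by 2.71 on the log2 scale (SE 0.454). Of 32 type I interferon genes, 0 passed over all genes and 0 adjusted over the list alone, at a median of −0.41 (camera adjusted p 3.03e-06, and adjusted p = 0.515 with an estimated correlation). The count with brentuximab vedotin was 42 without untreated replicate 1, 1 without treated replicate 1 or 3, and 0 without treated replicate 2 or untreated replicate 2 or 3.

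With ibrutinib in U2940, 1 of 33 NF-kB targets rose and 15 fell over all genes, and 2 and 17 adjusted over the list alone (camera adjusted p 2.04e-12, and adjusted p = 0.256 with an estimated correlation). EBI3 fell 2.56-fold, the chemokine CCL5 2.48-fold and, among cytokines, IL10 from 22.5 ± 0.807 to 7.02 ± 3.48. Of 32 B-cell genes, 11 rose and 2 fell over all genes, and 14 and 6 adjusted over the list alone (camera adjusted p 0.000195, and adjusted p = 0.109 with an estimated correlation). SYK, a B-cell receptor kinase, rose from 510.9 ± 40.9 to 1363 ± 284 and VPREB3 3.77-fold. Of 21 interferon gamma genes, 4 fell over all genes and 9 adjusted over the list alone (camera adjusted p 4.96e-07, and adjusted p = 0.366 with an estimated correlation). The largest rises were RASSF6 (2.58), the scaffold IQGAP2 (2.40), ADGRG5 (2.2) and PALLD (2.17), and the largest falls SYNPO (−2.09), STAT5A (−1.90), the vault RNA VTRNA1-2 (−1.84) and HMSD (−1.81). ADGRG5 lost its call without ibrutinib replicate 1 (limma-trend adjusted p 0.0752) or untreated replicate 2 (0.0516). SYNPO and STAT5A lost theirs without ibrutinib replicate 1 (0.206 and 0.12) or 3 (0.134 and 0.1) and without untreated replicate 1 (0.103 and 0.0634), 2 (0.134 and 0.106) or 3 (0.109 and 0.115). MS4A1 (−0.43, limma-trend adjusted p 0.0261) lost its call without ibrutinib replicate 1 (0.118) or untreated replicate 2 (0.111) or 3 (0.107). The count of 904 was 470 without ibrutinib replicate 1, 565 without untreated replicate 2 and 583 without untreated replicate 3.

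Prednisone in U2940 lowered NF-kB targets. Of 33 NF-kB targets, 20 fell over all genes and 21 adjusted over the list alone (camera adjusted p 1.5e-10, and adjusted p = 0.272 with an estimated correlation). EBI3 fell from 58.6 ± 7.78 to 7.05 ± 1.14, and LTA, a lymphotoxin gene, from 237.2 ± 3.22 to 57.4 ± 9.27. Of 13 chemokines and cytokines, 1 rose and 5 fell over all genes and adjusted over the list alone (camera adjusted p 0.00939, and adjusted p = 0.256 with an estimated correlation). Of 19 checkpoint genes, 9 fell over all genes, and 1 rose and 9 fell adjusted over the list alone (camera adjusted p 0.00249, and adjusted p = 0.355 with an estimated correlation), with the costimulatory ligand CD80 down 4.98-fold. Of 24 glucocorticoid receptor targets, 10 rose and 3 fell over all genes, and 10 and 4 adjusted over the list alone (camera adjusted p 0.0477, and adjusted p = 0.496 with an estimated correlation), with 6 up and 4 down under scaling outside ribosomal RNA. TSC22D3 rose 2.78-fold and BCL2L11 2.68-fold. Of 60 histone genes 37 fell over all genes and 42 adjusted over the list alone, and of 34 replication genes 15 fell and 1 rose over all genes, and 19 and 1 adjusted over the list alone (camera adjusted p 1.14e-14 and 5.93e-07, and adjusted p = 0.34 and 0.29 with an estimated correlation), and under that scaling 24 replication genes fell and 0 rose. The largest rises were CD38, a B-cell surface enzyme (15.1 ± 8.9 to 113.7 ± 42.8), COL7A1 (2.65), LAMA5 (2.65) and XYLT1 (2.50), and the largest falls the nuclear receptor RXRA (−3.87), the proline enzyme PYCR1 (−3.35), GPR183 (−3.12) and VASH2 (−2.98). Without untreated replicate 3, COL7A1 stood at 1.67 and LAMA5 at 1.46, and LAMA5 lost its call without prednisone replicate 3 (limma-trend adjusted p 0.0544). MYC fell from 541.1 ± 30.3 to 194.1 ± 7.98 and TNFRSF8 by 2.47 on the log2 scale. MS4A1 rose (0.40), a call lost without prednisone replicate 2 (limma-trend adjusted p 0.0554) and with scaling outside ribosomal RNA (0.063), and its log2 fold change was 0.23 without untreated replicate 1.

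In HDLM2, most NF-kB targets and chemokines that passed with brentuximab vedotin rose. CCL22 rose 14.5-fold from a mean of 216.4 to 3054 units (log2 fold change 3.85, SE 0.173, limma-trend adjusted p 6.41e-10), CCL19, a lymph node chemokine, from 3.17 ± 2.75 to 95.7 ± 22.4, the cytokine IL9 12.6-fold and SPOCK2 9.32-fold. The largest falls were PMCH (−3.83), the growth factor IGF1 (−2.64), FOXB1 (−2.61) and MIR4435-2HG (−2.56). Of 33 NF-kB targets, 26 rose over all genes, and 27 rose and 2 fell adjusted over the list alone (camera adjusted p 2.04e-17, and adjusted p = 0.256 with an estimated correlation), with the apoptosis inhibitor BIRC3 at 4.02-fold and the adhesion receptor ICAM1 at 3.83-fold. Of 20 chemokines and cytokines, 12 rose and 2 fell over all genes, and 13 and 2 adjusted over the list alone (camera adjusted p 3.1e-06, and adjusted p = 0.317 with an estimated correlation). Of 16 genes of MHC class I presentation, 13 rose over all genes and 14 adjusted over the list alone (camera adjusted p 1.41e-08, and adjusted p = 0.282 with an estimated correlation), and scaling outside ribosomal RNA left 7 up. Of 34 mitosis genes, 24 rose over all genes and 26 adjusted over the list alone (camera adjusted p 1.14e-14, and adjusted p = 0.318 with an estimated correlation). AURKA, a spindle kinase, rose from 78.8 ± 3.22 to 226.8 ± 9.87 and the mitotic cyclin CCNB1 2.79-fold. By contrast 21 of 34 replication genes fell over all genes and 25 adjusted over the list alone, and 55 of 62 histone genes fell over all genes and 59 adjusted over the list alone (camera adjusted p 1.26e-10 and 1.29e-27, and adjusted p = 0.281 and 0.317 with an estimated correlation). Of 15 tubulin genes, 4 rose and 1 fell over all genes and adjusted over the list alone, with TUBB2A from 120.2 ± 25.9 to 560.7 ± 24 (camera adjusted p 0.26), and the list's median was near 0 and turned to −0.22 with scaling outside ribosomal RNA, against a mean of 0.40. The ribosomal RNA share of these libraries was 87.3%, above all untreated ones, whose mean was 58.4%, and the count of 3324 genes was 1931 with that share as a covariate.

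Prednisone in HDLM2 gave the largest count of the 16 comparisons. All 34 mitosis genes and all 34 replication genes fell, over all genes and adjusted over the list alone, and 61 of 62 histone genes did (camera adjusted p 2.7e-24, 8.51e-19 and 1.57e-32, and adjusted p = 0.272, 0.235 and 0.29 with an estimated correlation). PLK1, a mitotic kinase, fell from 224.7 ± 18.4 to 42.5 ± 7.72 and H2BC3 from 128.3 ± 21.7 to 14.1 ± 6.82. Of 83 ribosomal protein genes, 81 fell over all genes and adjusted over the list alone (camera adjusted p 6.33e-16, and adjusted p = 0.464 with an estimated correlation), 71 with scaling outside ribosomal RNA. Of 33 NF-kB targets, 4 rose and 23 fell over all genes, and 5 and 23 adjusted over the list alone (camera adjusted p 8.85e-05, and adjusted p = 0.451 with an estimated correlation), with BIRC3 down 4.89-fold. Of 29 glucocorticoid receptor targets, 11 rose and 6 fell over all genes, and 12 and 6 adjusted over the list alone (camera adjusted p 0.0476, and adjusted p = 0.372 with an estimated correlation). TSC22D3 rose 3.13-fold. The long noncoding RNA NEAT1 rose from 2839 ± 1300 to 34540 ± 11100, PMEPA1 from 3.05 ± 3.76 to 43.4 ± 6.77, EGR2 from 3.77 ± 4.36 to 40.7 ± 8.86 and AS3MT from 2.10 ± 3.44 to 19.5 ± 9.05. The largest falls were LTB (67.7 ± 49.2 to 1.23 ± 0.448), FRG2EP (86.0 ± 67.9 to 2.09 ± 0.931), the chemokine receptor CCR8 (42.6 ± 16.7 to 1.73 ± 0.599) and GLT1D1 (−3.75), whose call was lost without untreated replicate 2 (limma-trend adjusted p 0.0537). TNFRSF8 fell from 1680 ± 201 by 1.26 on the log2 scale. These libraries held the lowest ribosomal RNA share of the line, 14.5%, against 58.4% untreated.

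Rituximab passed 0 genes in HDLM2 by limma-trend and ibrutinib 63, and both counts turned on untreated replicate 1. Without it, rituximab passed 1366 and ibrutinib 2299, and the ibrutinib count was 3 without untreated replicate 2 and 0 without untreated replicate 3 or any ibrutinib replicate. With rituximab, 0 of 33 NF-kB targets passed over all genes and 2 fell adjusted over the list alone, at a median of −0.32 (camera adjusted p 2.22e-08, and adjusted p = 0.318 with an estimated correlation). With ibrutinib, 3 of 33 NF-kB targets fell over all genes and 20 adjusted over the list alone (camera adjusted p 1.19e-14, and adjusted p = 0.256 with an estimated correlation). Among them TRAF1, a TNF receptor adaptor, went from 687.1 ± 173 to 346.1 ± 23 (limma-trend adjusted p 0.0116), a call lost without ibrutinib replicate 1 (0.0767), 2 (0.229) or 3 (0.0803) or untreated replicate 3 (0.105). Of 20 chemokines and cytokines, 1 fell over all genes and 14 adjusted over the list alone (camera adjusted p 1.06e-09, and adjusted p = 0.256 with an estimated correlation). The largest changes with ibrutinib were FAM78A (1.76), RESF1 (0.72), ST6GALNAC6 (0.64) and ZFAND3 (0.54) up, and CYP4Z1 (−1.89), GCSAM (−1.65), MYC (−1.29) and the carbonic anhydrase CA9 (−1.25) down. All 8, with limma-trend adjusted p of 0.0454 to 0.0498, lost their calls without ibrutinib replicate 1 (0.152 to 0.177), 2 (0.229 to 0.253) or 3 (0.142 to 0.173) or untreated replicate 2 (0.315 to 0.444) or 3 (0.256 to 0.309).

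In L428, prednisone lowered genes of MHC class II presentation. Of 13 tested, 10 fell over all genes and adjusted over the list alone (camera adjusted p 4.3e-08, and adjusted p = 0.117 with an estimated correlation). HLA-DQA1 went from 285.8 ± 9.74 to 159.5 ± 3.31 and the processing protease CTSS from 230.8 ± 30.5 to 110.5 ± 7.95. CCL17 fell 6.94-fold from 1240 ± 163 to 177.5 ± 17.9 (log2 fold change −2.79, SE 0.0838, limma-trend adjusted p 4.79e-19), and MYH8 (−3.25), H2AB2 (−2.78) and TACC2 (−2.77) fell from lower levels. H2AB2 (limma-trend adjusted p 0.0261) lost its call without untreated replicate 1 (0.061), 2 (0.063) or 3 (0.0741) and stood at −1.76 without prednisone replicate 1. TSC22D3 rose 4.70-fold, TLE3 4.19-fold, BCL2L11 4.09-fold and DHRS2 4.03-fold. Of 25 glucocorticoid receptor targets, 8 rose and 5 fell over all genes and adjusted over the list alone (camera adjusted p 0.0306, and adjusted p = 0.317 with an estimated correlation), with FKBP5, a receptor cochaperone, at 3.49-fold, and the list's median of 0.04 turned to −0.09 with scaling outside ribosomal RNA, against a mean of 0.35. Of 31 NF-kB targets, 14 rose and 5 fell over all genes, and 16 and 5 adjusted over the list alone (camera adjusted p 0.00175, and adjusted p = 0.235 with an estimated correlation), with the inhibitor NFKBIA at 2.35-fold.

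Ibrutinib in L428 passed 164 genes, and 55, 78 and 78 without ibrutinib replicates 1, 2 and 3, and 104 and 56 without untreated replicates 1 and 3. Of 82 ribosomal protein genes, 19 fell over all genes and 58 adjusted over the list alone, at a median of −0.22 (camera adjusted p 7.17e-36, and adjusted p = 0.272 with an estimated correlation), and with scaling outside ribosomal RNA 30 fell. Of 32 type I interferon genes, 2 rose over all genes and 7 adjusted over the list alone (camera adjusted p 1.5e-10, and adjusted p = 0.272 with an estimated correlation). The ERK phosphatase DUSP4 fell from 71.5 ± 12 to 31.8 ± 5.32 (limma-trend adjusted p 6.05e-05). The other largest changes were THBS1 (1.06), SHROOM1 (0.92), OAS3, an antiviral synthetase (0.85), and RRAD (0.78) up, and GJB2 (−1.52), PPP2R3A (−1.35) and CYP1B1 (−1.11) down. Of these, RRAD and DUSP4 kept their calls in every fit without 1 library. GJB2 and PPP2R3A lost theirs without ibrutinib replicate 2 (limma-trend adjusted p 0.115 and 0.0985) or untreated replicate 3 (0.0707 and 0.0729), and OAS3 without untreated replicate 3 (0.0715). CYP1B1 lost it without ibrutinib replicate 1 (0.0572), 2 (0.127) or 3 (0.0609) or untreated replicate 3 (0.25). THBS1 and SHROOM1 lost theirs without ibrutinib replicate 1 (0.0856 and 0.144), 2 (0.203 and 0.0985) or 3 (0.211 and 0.117) or untreated replicate 2 (0.229 and 0.115) or 3 (0.228 and 0.146).

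Brentuximab vedotin in L428 passed 3 genes, SEMA5B (1.49, SE 0.269), the kinase STK10 (0.62) and ARF3 (0.38), all upwards, with 908 at an unadjusted p under 0.05. All 3 lost their calls (limma-trend adjusted p 0.0169, 0.00716 and 0.0127) without treated replicate 1 (0.141, 0.101 and 0.121) or 2 (0.0666 each) or untreated replicate 2 (0.128, 0.114 and 0.128), and SEMA5B and ARF3 without treated replicate 3 (0.101 and 0.0709). All 3 also lost them with the ribosomal share as a covariate (0.326, 0.0679 and 0.0679). The count was 117 without untreated replicate 3, 20 without untreated replicate 1, 1 without treated replicate 2, and 0 without treated replicate 1 or untreated replicate 2. Of 25 interferon gamma genes, 0 passed over all genes, and 1 rose and 12 fell adjusted over the list alone (camera adjusted p 8.07e-10, and adjusted p = 0.272 with an estimated correlation). With rituximab, 0 of 25 passed over all genes and 2 rose adjusted over the list alone, at a median of 0.21 (camera adjusted p 9.47e-12, and adjusted p = 0.256 with an estimated correlation).

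Prednisone moved some genes alike in all 4 lines. Of 11266 genes tested in all, 104 rose and 288 fell in every line. If the lines were independent, 5.42 and 11.2 would do so, as scaled to the 15246 genes tested in at least 1 line. TSC22D3 rose by 3.04, 1.47, 1.65 and 2.23 on the log2 scale in K1106P, U2940, HDLM2 and L428, BCL2L11 by 1.77, 1.42, 1.25 and 2.03, and the autophagy gene GABARAPL1 by 1.28, 1.64, 1.43 and 1.71. KLHL3 (1.99, 1.27, 1.39 and 1.1) and ZNF862 (1.41, 1.35, 1.11 and 1.42) also rose, and the mitochondrial ribosome gene MRPL54 fell (−1.17, −1.23, −1.29 and −1.23). MRPL54 in U2940 was −0.46 without prednisone replicate 1 (limma-trend adjusted p 0.4) and lost its call without untreated replicate 1 (0.0851), 2 (0.166) or 3 (0.0645), and in L428 without untreated replicate 3 (0.0594). KLHL3 lost it in U2940 without prednisone replicate 1 (0.0649), 2 (0.0904) or 3 (0.0571) or untreated replicate 2 (0.0546) or 3 (0.169), and in L428 without untreated replicate 3 (0.0685). ZNF862 lost it in K1106P without prednisone replicate 1 (0.0515) or untreated replicate 3 (0.0566), in U2940 without prednisone replicate 1 (0.0658) or 3 (0.103) or untreated replicate 1 (0.091), and in L428 without untreated replicate 2 (0.182) or 3 (0.0638). With ibrutinib 6 genes rose and 20 fell in 3 lines, among them TRPV2 up (1.14, 1.03 and 0.54 in K1106P, U2940 and L428) and MYC down (−0.55, −1.29 and −0.58 in U2940, HDLM2 and L428). MYC in HDLM2 lost its call (limma-trend adjusted p 0.0498) without ibrutinib replicate 1 (0.177), 2 (0.253) or 3 (0.142) or untreated replicate 2 (0.337) or 3 (0.256), and TRPV2 in L428 without untreated replicate 3 (0.0631). With rituximab and with brentuximab vedotin 0 genes passed in 3 or more lines.

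Tested directly, each drug's effect differed between lines at many genes. The limma-trend F test passed 1866 of 14480 genes for rituximab, 1187 of 14575 for brentuximab vedotin, 2507 of 14767 for ibrutinib and 4585 of 14841 for prednisone. For rituximab the genes with the smallest p included SERPINB1, a protease inhibitor (1.93 in K1106P and 0.01, −0.03 and −0.12 in U2940, HDLM2 and L428), and ARID3A, a B-cell transcription factor (2.64, 0.25, −0.08 and −0.09). For brentuximab vedotin they included the actin bundler FSCN1 (2.92 in HDLM2, against 0.23, −0.60 and 0.01 in K1106P, U2940 and L428) and the histone methyltransferase EZH2 (1.09, against −0.10, −0.08 and 0.02). For ibrutinib the kinase HIPK2 (3.27 in K1106P) and the interleukin 13 receptor chain IL13RA1 (3.25) led, and for prednisone MKI67 (−1.70, −0.52, −1.52 and −0.17 in K1106P, U2940, HDLM2 and L428). In the same order of drugs the counts were 1562, 981, 2694 and 4189 without replicate 1, 458, 515, 599 and 1788 without replicate 2, and 525, 330, 516 and 1696 without replicate 3.

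MicroRNA calls were few. In K1106P rituximab raised 2 of 507, miR-155-5p from 1363 ± 578 to 16110 ± 12600 units (log2 fold change 3.40, SE 0.828, limma-trend adjusted p 0.0124) and miR-146a-5p from 8971 ± 3100 to 46970 ± 36300 (2.18, SE 0.485, limma-trend adjusted p 0.00466), both linked to NF-kB and immune activation. With the library size of the gene table neither passed, at 1.57 and 0.34 (limma-trend adjusted p 0.678 and 0.784 for hsa-miR-155-5p and hsa-miR-146a-5p). Both were also lost without rituximab replicate 3 (2.80 and 1.59, limma-trend adjusted p 0.46 each) or untreated replicate 1 (0.0859 and 0.121) or 3 (0.191 and 0.115). Both belong to the list of microRNAs described as acting on PD-L1, of which 2 rose over all microRNAs in that comparison (camera adjusted p 0.177). Of 8 let-7 members, 0 passed over all microRNAs with rituximab or prednisone in K1106P, and 3 rose with each drug adjusted over the list alone (camera adjusted p 0.00217 each, and adjusted p = 0.673 with an estimated correlation). The count of 2 was 0 without rituximab replicate 3, 1 without untreated replicate 1 or 3, and 4 without untreated replicate 2.

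Ibrutinib in K1106P passed 6 microRNAs, and all 4 that the rule names lost their calls with the library size of the gene table, hsa-miR-7847-3p (7.56, then limma-trend adjusted p 0.139), hsa-miR-3175 (3.42, then 0.251), hsa-miR-574-5p (3.27, then 0.236) and hsa-miR-3960 (−1.47, then 0.236). The count was 12 without ibrutinib replicate 1, 2 and 3 without ibrutinib replicates 2 and 3, and 1 without untreated replicate 3. Without ibrutinib replicate 2, hsa-miR-3175 (limma-trend adjusted p 0.068), hsa-miR-574-5p (0.0596) and hsa-miR-7847-3p (0.178) lost their calls, and without untreated replicate 3 all 4 did (0.2, 0.0706 and 0.2, and 0.192 for hsa-miR-3960). The calls of hsa-miR-7847-3p and hsa-miR-3960 were also lost without ibrutinib replicate 3 (limma-trend adjusted p 0.169 and 0.273) or untreated replicate 1 (0.257 and 0.185), the first without ibrutinib replicate 1 (0.0596) and hsa-miR-3960 without untreated replicate 2 (0.234). Prednisone in HDLM2 passed 6, with hsa-miR-574-5p (3.27), hsa-miR-1246 (2.81) and hsa-miR-619-5p (2.80) up, and hsa-miR-4492 from 13360 ± 7950 to 1066 ± 531 (−3.55, SE 0.631, limma-trend adjusted p 3.84e-05). The call of hsa-miR-4492 was kept in every fit without 1 library. Those of hsa-miR-574-5p, hsa-miR-1246 and hsa-miR-619-5p were lost without prednisone replicate 3 (limma-trend adjusted p 0.0838, 0.116 and 0.132), that of hsa-miR-574-5p also without untreated replicate 2 (0.0778). The calls of hsa-miR-1246 and hsa-miR-619-5p were lost without prednisone replicate 1 (limma-trend adjusted p 0.103 and 0.0905) or untreated replicate 3 (0.309 each), and hsa-miR-619-5p without untreated replicate 2 (0.184). The count was 14 without untreated replicate 1, 3 without untreated replicate 3 and 2 without prednisone replicate 3. With the library size of the gene table hsa-miR-574-5p, hsa-miR-1246 and hsa-miR-619-5p did not pass (limma-trend adjusted p 0.466, 0.442 and 0.683).

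In U2940 hsa-miR-29a-3p with rituximab went from 509.1 ± 10.4 to 5.92 ± 4.89 (limma-trend adjusted p 0.0459) and hsa-miR-29c-3p with brentuximab vedotin from 373 ± 175 to 9.11 ± 13.8 (limma-trend adjusted p 0.00487), levels of a few reads or none. The simulation for U2940 gave 2 wrong microRNA calls with the changed drug and 1 with an unchanged drug. The call of hsa-miR-29a-3p was lost without rituximab replicate 3 (limma-trend adjusted p 0.0947) or untreated replicate 1 (0.194), 2 (0.0929) or 3 (0.0981), and that of hsa-miR-29c-3p without untreated replicate 1 (0.0725) or 3 (0.0897). In the remaining comparisons limma-trend passed 0 microRNAs, with 15 to 44 at an unadjusted p under 0.05, and voom on recovered reads passed 24 with prednisone in K1106P, 5 with brentuximab vedotin in HDLM2, 2 with brentuximab vedotin in L428, 1 with prednisone in L428 and 0 in the others.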

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

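The tests of ribosomal share and of mixed cells in K1106P were chosen only after the result was seen. So were the scaling outside ribosomal RNA and the mislabelling test of HDLM2 untreated replicate 1. Predictions for the ribosomal tests in HDLM2 and for all splits of the libraries were written before the values of those tests were seen. The ribosomal covariate itself was added after seeing the data.

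The effects below differed between lines by the limma-trend F test on 3 degrees of freedom, with log2 fold changes in the order K1106P, U2940, HDLM2 and L428 and n = 3 per group. For rituximab, adjusted p was 0.00648 for PDCD1LG2 (−1.30, −0.01, −0.60 and 0.69), 0.000288 for TNFRSF8 (0.63, 1.21, −0.25 and 0.11), 2.99e-12 for SERPINB1 (1.93, 0.01, −0.03 and −0.12) and 2.99e-12 for ARID3A (2.64, 0.25, −0.08 and −0.09). It was 2.09e-10 for IRF4 (1.2, 0.27, −0.06 and 0.00), 1.92e-09 for SUB1 (1.65, 0.23, 0.11 and −0.05) and 1.33e-08 for SBNO2 (1.77, 0.15, −0.27 and 0.05). For brentuximab vedotin, limma-trend adjusted p was 0.0175 for CD274 (−0.23, −0.21, 1.04 and −0.69), 1.25e-10 for FSCN1 (0.23, −0.60, 2.92 and 0.01), 4.25e-10 for SLC20A1 (0.05, −0.02, 1.38 and 0.05) and 4.25e-10 for STK17B (−0.03, −0.05, 1.42 and −0.05). It was 9.78e-10 for EZH2 (−0.10, −0.08, 1.09 and 0.02) and 7.68e-09 for H2AZ1 (0.05, −0.02, 1.27 and −0.05).

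For ibrutinib, limma-trend F test adjusted p was 0.0404 for TNFRSF8 (0.49, −0.74, −0.31 and 0.10) and 0.0226 for BTK (0.08 and 0.18 in K1106P and U2940), which in L428 went from 0.787 to 3.70 units and was too low to test in either Hodgkin line alone. It was 8.55e-13 for HIPK2 (3.27, 0.61, 0.26 and −0.31), 8.55e-13 for IL13RA1 (3.25, 1.34, −0.30 and −0.09), 1.79e-08 for ASPM (−1.19, 0.16, 0.06 and −0.16), 2.75e-08 for ITPR1 (1.44, 0.43, −0.07 and 0.10) and 9.26e-08 for HIVEP3 (1.26, −0.70, 0.02 and −0.01). For prednisone, limma-trend adjusted p was 0.000327 for TNFRSF8 (−0.10, −2.47, −1.26 and 0.41), 4.31e-11 for MKI67 (−1.70, −0.52, −1.52 and −0.17), 4.31e-11 for ITPR1 (1.57, 0.72, −0.31 and 0.02) and 1.19e-09 for IL13RA1 (2.29, 0.94, −0.24 and −0.17). It was 1.31e-09 for PLXNC1 (1.93, 0.21, −0.16 and 0.53) and 1.31e-09 for CDCA7 (−0.77, 0.23, −2.40 and −0.30).

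Genes whose effect differed between lines numbered 1866, 1187, 2507 and 4585 for rituximab, brentuximab vedotin, ibrutinib and prednisone. Of 100 splits drawn within lines, the real one included, 8 gave as many genes as the real one for rituximab (highest other 2609). Of those 8, the other 7 kept or mirrored the K1106P labels, and the highest count among splits that did neither was 185. As many came from 1 split for brentuximab vedotin (highest other 1147), 3 for ibrutinib (2744) and 1 for prednisone (3657). Few splits gave as many there, but they remove each line's drug effect, so chance in line differences stays open for every drug.

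The ribosomal RNA share, outside the genes tested, was higher in each of the 3 treated libraries than in any untreated library of the line with prednisone in U2940 (mean 90.06%), with brentuximab vedotin in HDLM2 (87.32%) and L428 (84.04%), and with prednisone in L428 (85.85%). It was lower in each treated library than in any untreated one with all 4 drugs in K1106P and with prednisone in HDLM2. Groups of 3 were not tested for single libraries that stand apart.

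The genes changed by rituximab in K1106P came with a lower ribosomal RNA share, 74.0% against 89.5%. A first test, the slope of brentuximab vedotin on rituximab fold changes (0.202, SE 0.0598, against 0.553 from the shift in share), left this open. It was replaced once the next test's value was seen. With the log odds of the share as a covariate, the fold changes kept a median of 98.2% (SE 8.13), 3283 of 4267 genes were still called in the same direction, CD274 was −1.0 (SE 0.128) and PDCD1LG2 −1.40 (SE 0.178), which argues against the share as the whole cause. Cells of HDLM2 or L428 mixed into the cultures would bring their abundant genes. Those stood at a median of 0.177% or less of the other line's level (44 genes of HDLM2, highest 2.31%, and 39 of L428, highest 2.84%). U2940 cells stay open, because 1 gene marked that line and the test was narrowed after a first run. A response to the antibody remains a hypothesis, as other culture differences were not tested.

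The genes changed by prednisone in HDLM2 came with the lowest ribosomal share, 14.5% against 58.4%. With the covariate, fold changes kept a median of 88.5% (SE 6.55), and 3406 of 6462 genes their call and direction. The median SE went from 0.145 to 0.194. Shares did not overlap, so the slope leans on untreated replicate 1 (19.98%), of doubtful label. The share stays open, and culture differences were not tested.

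HDLM2 untreated replicate 1 lay apart from replicates 2 and 3, with a share of 19.98% and root mean square log2 distances of 0.618 and 0.556 to them, against 0.404 between them. Its own group ranked 3 among the 5 group means by distance (ibrutinib 0.252, rituximab 0.30, untreated 0.552). MS4A1 and BTK, the targets of rituximab and ibrutinib, were near 0 in untreated HDLM2 (1.23 and 0.583). Libraries with either drug may therefore resemble untreated ones. The rank cannot separate a mislabelled sample from both other untreated replicates being the odd ones. An added distance requirement in that test was dropped after its result was seen. The correlation over genes of its deviation with the change towards a lower share was 0.321 (SE 0.108), which leaves the share open, and no biological explanation was tested.

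For single comparisons 10 splits of 6 libraries are too few for a share under 0.05. The number of splits with as many genes as the real one, the real one included, was 1 in K1106P for rituximab (4267, highest other 1), ibrutinib (5123, highest other 0) and prednisone (3909, highest other 1), and 3 for brentuximab vedotin (1, highest other 1). In U2940 it was 2 for rituximab (3, highest other 7) and brentuximab vedotin (2, highest other 3), and 1 for ibrutinib (904, highest other 2) and prednisone (3435, highest other 0). In HDLM2 it was 1 for brentuximab vedotin (3324, highest other 0), ibrutinib (63, highest other 0) and prednisone (6462, highest other 0), and 10 for rituximab (0, highest other 615). The split with 615 put rituximab replicates 1 and 3 with untreated replicate 1, which follows the ribosomal share. In L428 it was 1 for brentuximab vedotin (3, highest other 0), ibrutinib (164, highest other 1) and prednisone (2892, highest other 1), and 10 for rituximab (0, highest other 12). For microRNAs it was 1 in K1106P for rituximab (2, highest other 0) and ibrutinib (6, highest other 0). It was 2 in U2940 for rituximab (1, highest other 5), 4 for brentuximab vedotin (1, highest other 1) and 2 in HDLM2 for prednisone (6, highest other 6). In the comparisons with 0 microRNAs it was 10, and the highest other was 6 for rituximab in HDLM2 5 for ibrutinib in U2940 and HDLM2, 3 for brentuximab vedotin in HDLM2 and rituximab in L428, 2 for prednisone in L428 and 0 in the others.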

How the results depend on the processing

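MicroRNA libraries held 2744 to 8773 reads, so that a level near 0 was a few reads or none. Simulated 4-fold microRNA changes were recovered at 66.7% in U2940 and 7.14% in L428. Depth was similar (4704 to 7956 and 3660 to 8370 reads), so it is not the only limit. DESeq2 and a size factor inside a count model were planned and not run, as the values are not whole counts. The settings added after seeing the data are listed with the processing above. Where a value below changed, the cause was not tested, except that fits with fewer libraries have less precision. Gene counts not given under a setting below stayed within 1.5 times of the reported one. For brentuximab vedotin, 0 of the reported genes were among the 4 in L428 with the ribosomal share as a covariate or the 1 in K1106P with voom. Among named genes and microRNAs, 5515 of the fits without 1 library left the call on its side, 843 lost it and 20 gained it, and with scaling outside ribosomal RNA these were 966, 86 and 4, and with the ribosomal share as a covariate 851, 203 and 2. Of 404 list tests, camera called 158, of which 0 passed with an estimated correlation (lowest adjusted p 0.106), 97 by fry in the same direction and 155 with the replicate block. The BCL2 family list with prednisone in HDLM2 reversed from camera (up, adjusted p 0.787) to fry (down, adjusted p 0.00228).

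Replicate numbers share only a number: the mean correlation of same-numbered libraries was 0.029, 0.0286, 0.00865 and 0.019 over genes in K1106P, U2940, HDLM2 and L428. Of 15 libraries, 11, 7, 6 and 10 correlated best with their own number, a hint from the data and not from the labels. With the replicate block the gene counts were 2 for brentuximab vedotin in K1106P, 35 for rituximab in U2940, 126 for ibrutinib in HDLM2 and 52 for brentuximab vedotin in L428, and the microRNA counts were 0 for rituximab in U2940, 5 for brentuximab vedotin and 10 for prednisone in HDLM2. Without a filter on low values, gene counts were 0 for brentuximab vedotin in K1106P, 10 for rituximab in U2940, 3 for ibrutinib in HDLM2 and 7 for brentuximab vedotin in L428. MicroRNA counts were then 1 and 2 for rituximab and ibrutinib in K1106P, 2 for rituximab in U2940, and 3 and 0 for brentuximab vedotin and prednisone in HDLM2. With only the 6 libraries of both groups, gene counts were 185 for brentuximab vedotin in K1106P, 18 and 0 for rituximab and brentuximab vedotin in U2940, 1767 and 0 for brentuximab vedotin and ibrutinib in HDLM2, and 57 and 296 for the same drugs in L428. MicroRNA counts were 2 and 21 for brentuximab vedotin and prednisone in K1106P, 0 and 0 for rituximab and brentuximab vedotin in U2940, 0 for prednisone in HDLM2 and 1 for brentuximab vedotin in L428. With a pseudocount of 0.1 the counts were 1 and 14 genes for rituximab and ibrutinib in HDLM2 and 0 microRNAs for rituximab in U2940. With the library size of the gene table, microRNA counts were 1 and 3 for rituximab and ibrutinib in K1106P, 0 and 4 for rituximab and prednisone in U2940 and 1 for brentuximab vedotin in L428. With voom on recovered reads, gene counts were 13 and 0 for rituximab and brentuximab vedotin in U2940, 2 for ibrutinib in HDLM2, and 1, 14 and 327 for rituximab, brentuximab vedotin and ibrutinib in L428. MicroRNA counts were 18, 37 and 24 for rituximab, ibrutinib and prednisone in K1106P, 2 for rituximab in U2940, 5 and 32 for brentuximab vedotin and prednisone in HDLM2, and 2 and 1 for the same drugs in L428. With scaling outside ribosomal RNA, gene counts were 0 for brentuximab vedotin in K1106P, 19 for ibrutinib in HDLM2 and 31 for brentuximab vedotin in L428, and with scaling to the microRNA total there were 2 for prednisone in U2940 and 1 for brentuximab vedotin in HDLM2. With the ribosomal share as a covariate, gene counts were 0 for brentuximab vedotin in K1106P and U2940, 1544 and 998 for prednisone in U2940 and L428, and 125, 1931, 340 and 3568 for rituximab, brentuximab vedotin, ibrutinib and prednisone in HDLM2. Without libraries of outlying ribosomal share, gene counts were 1169 and 1762 for rituximab and ibrutinib in HDLM2. MicroRNA counts were then 9, 3 and 9 for rituximab, ibrutinib and prednisone in K1106P, and 1, 1 and 15 for the same drugs in HDLM2.

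Leaving out 1 library at a time gave these ranges of genes for rituximab, brentuximab vedotin, ibrutinib and prednisone: 3220 to 3514, 0 to 1, 3682 to 5021 and 3049 to 3339 in K1106P, and 1 to 30, 0 to 42, 470 to 924 and 2601 to 3347 in U2940. They were 0 to 1366, 2769 to 3570, 0 to 2299 and 5002 to 6741 in HDLM2, and 0 to 0, 0 to 117, 55 to 124 and 2080 to 2781 in L428. For microRNAs they were 0 to 4, 0 to 1, 1 to 12 and 0 to 2 in K1106P, 0 to 2, 0 to 2, 0 to 3 and 0 to 1 in U2940, 0 to 0, 0 to 12, 0 to 3 and 2 to 14 in HDLM2, and 0 to 0, 0 to 1, 0 to 1 and 0 to 1 in L428. Between lines they were 458 to 1562, 330 to 981, 516 to 2694 and 1696 to 4189. For the untreated lines, the limma-trend F test adjusted p ran from 2.67e-13 to 1.51e-08 for BTK, 2.08e-12 to 0.000185 for CD274, 2.05e-11 to 4.94e-05 for MS4A1, 3.3e-09 to 2.92e-06 for NR3C1, 5.79e-11 to 2.41e-05 for PDCD1LG2 and 1.37e-10 to 6.31e-10 for TNFRSF8.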

Other observations

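The tests of host transcripts and of opposed drug effects were chosen only after the result was seen.

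Metabolic gene lists moved with several drugs. Of 25 cholesterol synthesis genes, 11 rose with rituximab in K1106P over all genes and 13 adjusted over the list alone (camera adjusted p 0.0035, and adjusted p = 0.32 with an estimated correlation), with the enzyme MVD at 2.02-fold, and scaling outside ribosomal RNA left 4 up. With brentuximab vedotin in HDLM2, 12 rose over all genes and adjusted over the list alone (camera adjusted p 3.03e-05, and adjusted p = 0.155 with an estimated correlation), among them SQLE (2.27-fold), and that scaling left 6 up and 3 down. With prednisone in HDLM2, 1 rose and 16 fell over all genes and adjusted over the list alone (camera adjusted p 0.0156, and adjusted p = 0.29 with an estimated correlation), and that scaling gave 4 up and 10 down. Of 21 glycolysis and hypoxia genes, 9 rose and 1 fell with rituximab in K1106P over all genes, and 10 and 1 adjusted over the list alone (camera adjusted p 0.00233, and adjusted p = 0.318 with an estimated correlation). With prednisone there, 5 rose and 8 fell by both adjustments (camera adjusted p 0.103), with the glycolytic enzymes HK2 (−1.70) and LDHA (−1.64) among the falls.

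Of 6 T-cell and NK-cell markers tested in K1106P, 3 fell with prednisone over all genes and adjusted over the list alone (camera adjusted p 0.0411, and adjusted p = 0.318 with an estimated correlation), and 1 rose and 2 fell with rituximab (camera adjusted p 0.254). Of 5 myeloid markers in K1106P, 4 rose and 1 fell with ibrutinib by both adjustments (camera adjusted p 0.125). With prednisone in HDLM2, 3 of 5 myeloid markers rose and 1 fell, and 2 of 7 T-cell and NK-cell markers rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p 0.354 and 0.262). Of 25 p53 target genes in K1106P, 5 rose and 4 fell with rituximab over all genes, and 6 and 4 adjusted over the list alone (camera adjusted p 0.6), and the sign of the median turned with scaling outside ribosomal RNA. CDKN1A, a cell cycle inhibitor, rose 2.21-fold. Of 8 complement regulators and Fc receptors, 0 rose and 4 fell with rituximab in K1106P over all genes, and 1 and 4 adjusted over the list alone (camera adjusted p 0.0704).

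Any rise of miR-155-5p with rituximab in K1106P may come with its host transcript MIR155HG, up by 1.77 on the log2 scale (88.2 ± 1.47 to 305 ± 37.6, SE 0.176, limma-trend adjusted p 2.35e-07). The miR-146a-5p host MIR3142HG had a log2 fold change of 0.044 (155.5 to 160.5, SE 0.124, limma-trend adjusted p 0.808). With the library size of the gene table neither microRNA passed, so whether either rose stays open. The test was planned for both together and split after its results were seen.

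Over genes in K1106P, log2 fold changes of rituximab and ibrutinib had a correlation of −0.0151 (SE 0.107), with a covariance of −0.00596. Simulated groups without any drug effect that share the untreated libraries gave a covariance of 0.0351. Their correlation of 0.499 is no measure for drugs with effects, whose fold changes spread more widely. The requirement that the value lie more than 2 standard errors from 0 was added after it was seen, and so whether both drugs had opposed effects stays open. Genes are not independent replicates.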
